A study of Homo sapiens with 8 samples.

How the data were processed

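RNA-seq libraries of poly(A) RNA from MV4;11 cells were analysed: 8 libraries in 4 conditions of 2, namely 0.1% DMSO, 500 nM I-BET151, 5 µM SGC0946 and both inhibitors. Conditions were taken from the sample labels. RNA was purified with an RNeasy kit and made into TruSeq libraries, per the labels' protocols. The submitters' processing notes name TopHat2, Bowtie2, HTSeq, edgeR and the hg19 genome build, without versions or roles. Strand and the treatment of multi-mapped reads are not given in the sources used here, so values of overlapping, antisense and near-identical genes are uncertain.

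The authors deposited 1 table of CPM values with a column per condition, each the mean of the condition's 2 libraries, for 12192 genes. Column sums were 711704.2 to 742570.6, less than the full scale of CPM, so the CPM were scaled to totals that include reads outside the listed genes. Every listed gene exceeded 1 CPM in at least 3 libraries, and 11999 did in at least 4. Genes below such a limit are not analysed here. A gene above 1 CPM only in the 2 libraries of 1 condition is therefore absent, whatever its change. Symbols came from Ensembl identifiers for 12149 genes and from RefSeq accessions for 29, 14 had no name and 6 shared a symbol with another. Coordinates are not printed, because the annotation at hand (GENCODE on GRCh38) is of another build than hg19. It was used only for gene lengths, which 12167 genes (99.8%) had.

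The deposited means were separated into libraries. A mean of 2 CPM values is a sum of 2 whole counts, each divided by its library total, so the library totals and counts were solved for jointly. All 12192 genes had exactly 1 solution in each of the 4 columns, with rebuilt means within 5e-12 CPM and totals within 1.9e-08 of whole numbers. Of values shifted by a relative 1e-06, 0% had a solution. On simulated data both totals were exact in 4 of 4 conditions and both counts in 3000 of 3000 genes. The separation does not say which library is replicate 1 or 2, so libraries were named A (deeper) and B (shallower) and were not paired. Library totals ran from 13843940 to 16900030 reads, 1 read being worth 0.0592 to 0.0722 CPM. Reads without molecular identifiers are not independent molecules.

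The libraries of a condition differed by more than counting noise, with chi-square per degree of freedom of 10.11 (DMSO), 11.07 (I-BET151), 4.77 (SGC0946) and 5.34 (combination), so none was a repeat deposit. The test was limma (lmFit and eBayes with a trended prior) on log2(CPM + 0.5) of the 8 libraries in 1 fit of condition means, with 4 residual and 6.31 prior degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg, with 0.05 as the threshold. A filter of 1 CPM in at least 2 libraries removed 0 genes. The comparisons were each treatment with DMSO, the combination with each single agent, the single agents with each other, and the interaction. On simulated reads of 12192 genes, the comparison of I-BET151 with DMSO called 65% of genes changed 1.5-fold, 93.8% of those changed 2-fold and 39 of 40 changed 4-fold, and 5 of 11964 unchanged genes. The interaction called 11 unchanged genes. The simulation gave every gene the same spread beyond counting noise, so these shares can overstate those of the real data.

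Before the data were examined, 20 gene lists, the test, its alternatives and the rule for named genes were fixed. The plan was not carried out in full: the count tests planned for whole reads, with edgeR and DESeq2, were not run. Lists with at least 5 tested members (18) were tested with camera at a preset inter-gene correlation of 0.01. The mitochondrially encoded list (0 of 13 members in the table) and the erythroid and megakaryocyte list (4 of 20) were not tested. Named genes are the 10 largest rises and 10 largest falls of each comparison with DMSO, and 5 and 5 of the others, among called genes with a mean of at least 5 CPM whose libraries did not overlap between conditions and which had a common symbol. MYC, BCL2, HOXA9, HOXA10, MEIS1, CDK6, MYB, HEXIM1, BRD2 and DOT1L are always included, with up to 4 called members of a list. Not every gene that the rule selects is reported here, and none was put in place of one left out. For shared libraries, 100 simulations of unchanged conditions gave the correlation and covariance that sharing alone produces.

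The alternatives were pseudocounts of 0.1 and 1, no filter and a filter of 5 CPM (10163 genes), median-of-ratios and quantile scaling, fits of only the conditions compared, a robust prior, an adjusted p under 0.01, a 2-fold minimum, leaving out each library, and for lists an estimated correlation and fry. Chosen after seeing the data were limma-voom on the separated reads, 2 blocks of libraries described in the closing section, the alternatives for overlaps of the combination against a single agent, and 21 gene families picked by symbol. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.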

Results

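RNA from MV4;11, an established human leukaemia cell line that carries an MLL (KMT2A) fusion, was measured by sequencing of poly(A) RNA under 4 conditions with 2 libraries each. Cells were kept in 0.1% DMSO, in 500 nM I-BET151, in 5 µM SGC0946, or in both inhibitors. I-BET151 blocks the bromodomains of the BET proteins, a family of chromatin readers. SGC0946 inhibits DOT1L, a histone H3 methyltransferase recruited by MLL fusion proteins. How long the cells were treated is not given in the sources used here, nor is it stated whether the conditions with an inhibitor also held DMSO, so a comparison with DMSO may include a difference in vehicle. The authors deposited the mean CPM (reads scaled to the library total) of each condition for 12192 genes, and each mean separated into the whole read counts of its 2 libraries. The libraries held 13843940 to 16900030 reads, of which 71.0% to 75.0% fell in the listed genes. Below, a mean ± SD is in CPM with n = 2, and the libraries of a condition are called A (deeper) and B (shallower), because their replicate numbers are not attached to the values. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of low genes, and carry limma's standard error (SE) and adjusted p. Nothing states that the 2 libraries of a condition came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The first principal component held 63% of the variance and separated the libraries with I-BET151 from those without it, and the next held 21.8% and separated those with SGC0946 from those without it.

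**Figure D1:**
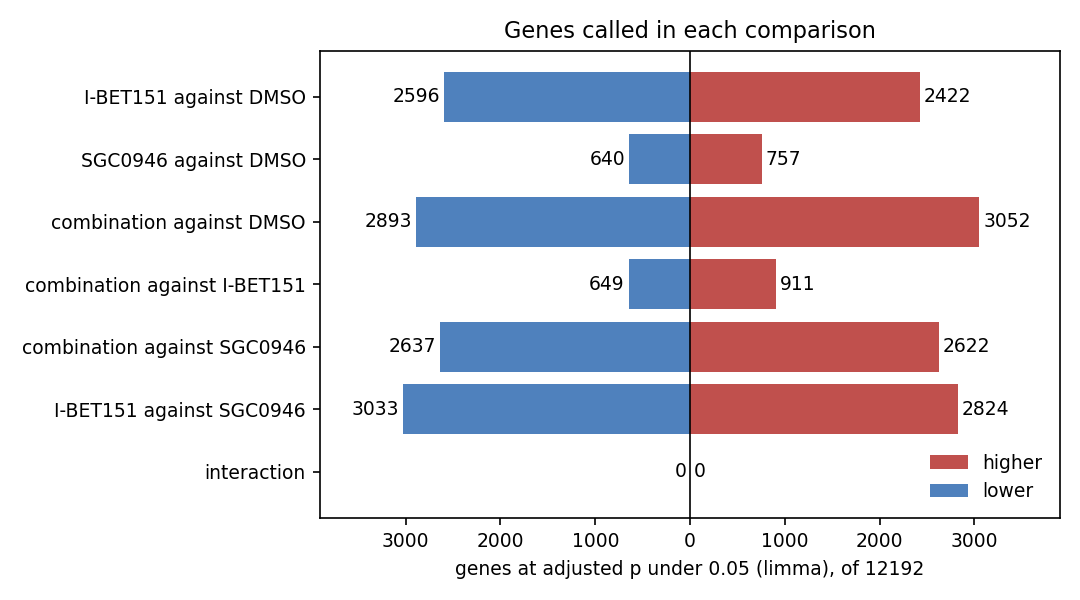
Number of genes (horizontal axis) at a limma adjusted p under 0.05 among 12192 tested, with genes higher in the condition named first to the right and lower ones to the left, for each comparison (vertical axis). The bars reach 5018 genes in all for I-BET151 and 1397 for SGC0946 against DMSO, and 0 for the interaction.

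The comparison of I-BET151 with DMSO asks what BET inhibition alone did. MYC, a transcription factor that drives growth, fell from 467 ± 16.4 to 98.9 ± 2.32 CPM (log2 fold change −2.23, SE 0.14, limma adjusted p = 5.77e-06). BCL2, which blocks apoptosis, fell from 233 ± 12.8 to 67.7 ± 6.49 CPM (log2 fold change −1.78, SE 0.12, limma adjusted p = 7.01e-06), and CDK6, a cell cycle kinase, from 617 ± 2.93 to 246 ± 36.1 CPM (log2 fold change −1.33, SE 0.10, limma adjusted p = 1.19e-05). HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose from 58.0 ± 2.41 to 219.6 ± 24.3 CPM (log2 fold change 1.91, SE 0.11, limma adjusted p = 4.48e-06), and BRD2 from 233 ± 1.76 to 382 ± 10.7 CPM. HOXA9 and HOXA10, homeobox genes of the MLL programme, rose by log2 fold changes of 0.76 and 0.71 (SE 0.11 and 0.10, limma adjusted p = 0.000449 and 0.000431). MEIS1 and DOT1L had log2 fold changes of −0.07 and −0.01 (SE 0.11 and 0.08, limma adjusted p = 0.67 and 0.967). MYB fell by 0.24 on the log2 scale (SE 0.08, limma adjusted p = 0.0407), a call that was lost without any of 7 of the 8 libraries (adjusted p up to 0.167).

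The largest rises with I-BET151 were those of EFR3B (log2 fold change 3.71), SAT1, a polyamine acetyltransferase (3.44), the histone gene H2AC6 (3.37), FGD6 (3.24), SERPINI1 (3.08), DPYSL3 (2.86), H2BC11 (2.82), SEMA6C (2.74), CAPN5 (2.71) and the creatine transporter SLC6A8 (2.71). Histone genes are seen in poly(A) RNA only through transcripts with a poly(A) tail. The largest falls were those of CCR2, a chemokine receptor of monocytes (−4.58), GRIP1 (−3.72), HSH2D (−3.62), LGALS12 (−3.47), MPEG1 (−3.02), B3GNT7 (−2.87), ADM2 (−2.78), CSPG4 (−2.77), TCF23 (−2.71) and INHBA (−2.68). Their SE lay between 0.12 and 0.54 and all 20 were called by limma (adjusted p from 2.22e-07 to 0.0025), with and without any single library.

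Among the gene lists fixed in advance, MYC targets of ribosome and nucleotide synthesis fell together: 33 of 41 members fell and 1 rose, with a median log2 fold change of −0.67 (camera adjusted p = 5.54e-10, and adjusted p = 0.571 with an estimated correlation). SLC19A1, a folate carrier, fell by 1.64 on the log2 scale, the nucleolar MYBBP1A by 1.42, CAD, which starts pyrimidine synthesis, by 1.30 and NOP16 by 1.24. Of 9 known markers of BET inhibition, 8 rose and 1 fell, with a median of 2.31 (camera adjusted p = 1.07e-06, and adjusted p = 0.272 with an estimated correlation), and 5 of the 9 are histone genes. Of 22 genes of monocyte, macrophage and granulocyte differentiation, 14 fell and 1 rose, with a median of −0.65 (camera adjusted p = 8.58e-05, and adjusted p = 0.571 with an estimated correlation), among them CSF1R, the receptor of a monocyte growth factor (−2.24), the scavenger receptor CD36 (−2.17) and MS4A7 (−2.11). Of 14 stem and progenitor genes 9 fell, with a median of −0.38 (camera adjusted p = 0.00729, and adjusted p = 0.571 with an estimated correlation), such as GATA2 (−1.77) and SPI1 (−0.81). Of 28 mitosis genes 15 rose and 1 fell, with a median of 0.37 (camera adjusted p = 0.000296, and adjusted p = 0.583 with an estimated correlation), such as NCAPG (0.81), a condensin subunit, and TTK (0.58), a spindle checkpoint kinase. Of 24 unfolded protein and amino acid stress genes 9 fell and 1 rose, with a median of −0.44 (camera adjusted p = 0.012, and adjusted p = 0.571 with an estimated correlation). Without DMSO A the medians of the mitosis and stress lists were 0.231 and −0.221, and without I-BET151 A that of the stem and progenitor list was −0.666, each still called. Adjusted over the list alone, 33 MYC targets, 14 differentiation genes and 9 stem and progenitor genes fell, and 15 mitosis genes rose. Of the MLL fusion targets, 9 of 21 fell and 2 rose (median −0.18, camera adjusted p = 0.0739). None of the other 11 lists was called, with camera adjusted p from 0.115 for the p53 targets, of which 10 of 22 rose and 1 fell, to 0.589 for the NF-kB and cytokine genes, of which 2 of 13 rose and 2 fell.

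In all, limma called 5018 of 12192 genes for I-BET151 against DMSO, 2422 higher and 2596 lower, and 1016 of them changed at least 2-fold. At an adjusted p under 0.01 the count was 3187. No list kept its call with an estimated correlation in this or any other comparison. The loss of calls does not measure correlation among members alone. Camera with an estimated correlation also uses only the 4 residual degrees of freedom, which leaves less power than the preset. With SGC0946 the p53 targets had an estimated correlation of 0.01, equal to the preset, yet went from camera adjusted p = 0.0198 to 0.191.

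**Figure D2:**
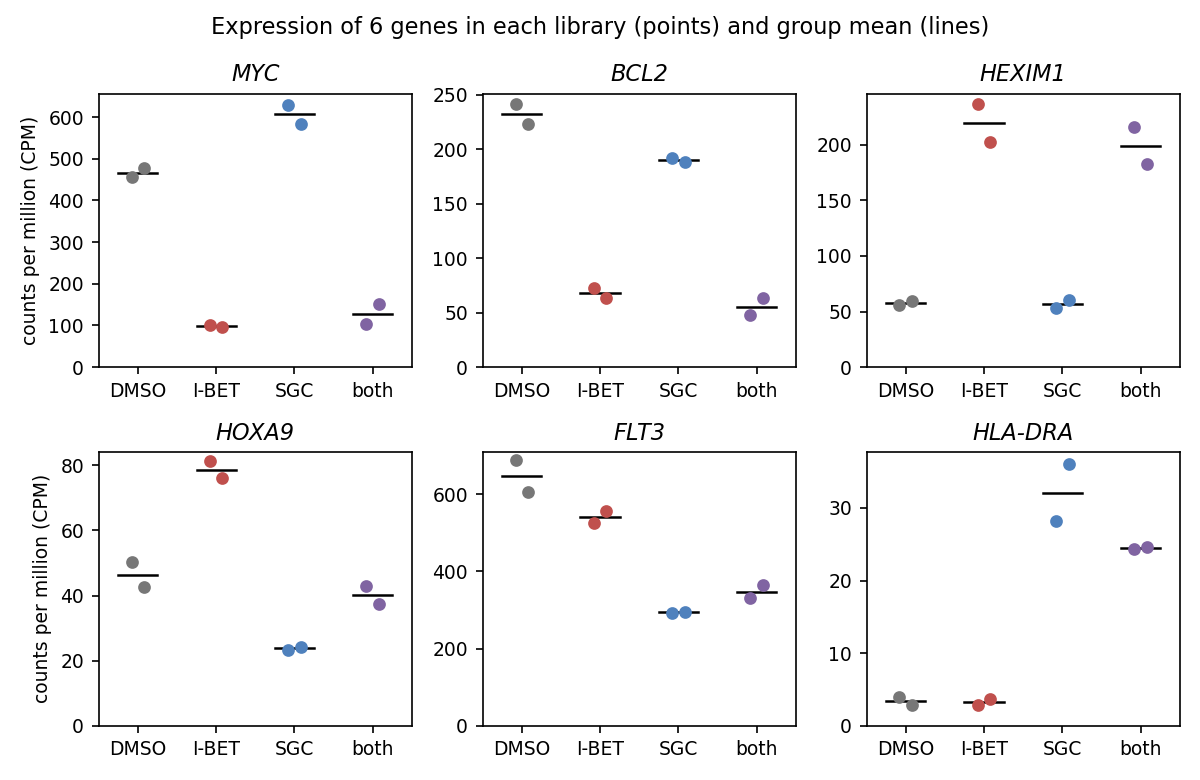
Expression in CPM (vertical axes, linear, from 0) of 6 genes in each of the 8 libraries (points) with the mean of the 2 libraries of a condition (lines), by condition (horizontal axes). MYC and BCL2 are low in the 4 libraries with I-BET151, HOXA9 and FLT3 are lower with SGC0946 than without it at either level of I-BET151, and HLA-DRA reaches 32.1 CPM with SGC0946 against 3.40 CPM in DMSO.

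The comparison of SGC0946 with DMSO asks what DOT1L inhibition alone did. The MLL fusion targets fell: 11 of 21 members fell and none rose, with a median log2 fold change of −0.44 (camera adjusted p = 6.67e-12, and adjusted p = 0.181 with an estimated correlation). HOXA9 fell from 46.4 ± 5.56 to 23.7 ± 0.667 CPM (log2 fold change −0.95, SE 0.11, limma adjusted p = 0.000909) and HOXA10 from 40.1 ± 0.0231 to 18.6 ± 0.829 CPM (log2 fold change −1.08, SE 0.10, limma adjusted p = 0.000353). FLT3, a receptor tyrosine kinase of blood progenitors, fell from 648 ± 58.7 to 294 ± 3.36 CPM (log2 fold change −1.14, SE 0.09, limma adjusted p = 0.00023). MEF2C fell by 1.26 and PBX3 by 0.99 on the log2 scale. MEIS1 fell by 0.50 and CDK6 by 0.63 (limma adjusted p = 0.0204 and 0.00433), but MEIS1 lost its call without DMSO A, SGC0946 A or SGC0946 B (adjusted p up to 0.118) and CDK6 without SGC0946 B (adjusted p = 0.0543). MYC stood at 607 ± 32.9 CPM against 467 ± 16.4 CPM (log2 fold change 0.38, SE 0.14, limma adjusted p = 0.123). BCL2, MYB, HEXIM1, BRD2 and DOT1L had log2 fold changes of −0.29, −0.23, −0.03, 0.05 and −0.19 (limma adjusted p = 0.161, 0.114, 0.894, 0.728 and 0.159).

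Genes of MHC class II antigen presentation rose: 7 of 8 members rose, with a median log2 fold change of 1.5 (camera adjusted p = 1.85e-10, and adjusted p = 0.128 with an estimated correlation). HLA-DRA rose from 3.40 ± 0.715 to 32.1 ± 5.57 CPM (log2 fold change 3.06, SE 0.18, limma adjusted p = 2.72e-05), and CIITA, the transactivator of these genes, from 5.70 ± 1.63 to 18.05 ± 0.499 CPM (log2 fold change 1.61, SE 0.21, limma adjusted p = 0.00161). HLA-DRB1 and HLA-DRB5, which are closely similar in sequence and can share reads, had log2 fold changes of 1.34 and 1.36. Of 33 DNA replication genes 24 fell and none rose, with a median of −0.45 (camera adjusted p = 2.75e-20, and adjusted p = 0.128 with an estimated correlation), such as RRM2, a ribonucleotide reductase subunit (−0.85), PRIM1 (−0.73) and CDC45 (−0.73). Of 28 mitosis genes 13 fell, with a median of −0.30 (camera adjusted p = 4.27e-10, and adjusted p = 0.223 with an estimated correlation), with KIF2C at −0.57 and CDK1 at −0.56, the latter not called without SGC0946 A (limma adjusted p = 0.0725). With median-of-ratios and quantile scaling 9 and 6 mitosis genes fell. Adjusted over the list alone, 14 MLL fusion targets, 29 replication genes and 18 mitosis genes fell, and 7 MHC class II genes rose.

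Of 24 unfolded protein and amino acid stress genes 13 fell and none rose, with a median of −0.94 (camera adjusted p = 1.85e-10, and adjusted p = 0.128 with an estimated correlation). Adjusted over the list alone, 15 fell. CHAC1, a glutathione-degrading enzyme induced by this stress, fell from 40.5 ± 17.9 to 1.79 ± 0.0217 CPM (log2 fold change −4.09, SE 0.46, limma adjusted p = 0.00074), and PSAT1, an enzyme of serine synthesis, from 372 ± 167 to 79.2 ± 5.52 CPM (log2 fold change −2.15, SE 0.25, limma adjusted p = 0.000861). The DMSO libraries differed in these genes: over the 13 members that fell, library A was higher than B by a median log2 difference of 0.92. In I-BET151 library A was lower than B, at −0.47. Of 22 p53 targets 6 fell (median −0.12, and −0.052 without DMSO B, camera adjusted p = 0.0198, and adjusted p = 0.191 with an estimated correlation). They include SESN2 (−2.29), also a gene of amino acid stress, and the cell cycle inhibitor CDKN1A (−1.03).

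The 10 largest falls with SGC0946 were those of CHAC1 (log2 fold change −4.09), ADM2 (−3.53), the cystine transporter SLC7A11 (−2.55), SESN2 (−2.29), PSAT1 (−2.15), PCK2 (−2.03), CBS (−1.86), ALDH1L2 (−1.82), CTH (−1.75) and PHGDH (−1.67). Of these, 6 lost the limma call when a library was left out. SLC7A11 lost it without DMSO A or either SGC0946 library (adjusted p up to 0.147). CBS and CTH lost it without DMSO A or any library of SGC0946 or of the combination (up to 0.169 and 0.22). PCK2, ALDH1L2 and PHGDH lost it without either SGC0946 library (up to 0.0662, 0.0721 and 0.0794). The 10 largest rises, all called without any single library, were those of LSP1 (3.10), HLA-DRA (3.06), SERPINB10 (2.58), CHI3L1 (2.57), CYP1B1 (2.56), SAMSN1 (2.46), the coagulation factor gene F13A1 (2.43), the metalloproteinase gene MMP2 (2.21), KCNQ3 (2.11) and PLEKHO1 (2.09).

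Weaker list results were less firm. Differentiation genes of the monocyte and granulocyte lineage moved both ways, with 6 of 22 higher and 2 lower (median 0.20, camera adjusted p = 0.0341, and adjusted p = 0.54 with an estimated correlation). CD86 (1.79) and CSF1R (1.33) rose, CSF1R not being called without SGC0946 A (limma adjusted p = 0.0593). The interferon response (4 of 27 higher, median 0.17, camera adjusted p = 0.0341), lymphoid markers (2 of 6 higher, median 0.30, camera adjusted p = 0.0353) and cholesterol synthesis (2 of 24 lower, median −0.16, camera adjusted p = 0.0214) had adjusted p = 0.35, 0.223 and 0.569 with an estimated correlation. Without a library these calls ended: the differentiation list without DMSO B or SGC0946 A (camera adjusted p = 0.163 and 0.0599), the interferon list without DMSO B or SGC0946 B (0.177 and 0.0647), the lymphoid list without DMSO A or SGC0946 A (0.0874 and 0.0649), and cholesterol synthesis without DMSO B, where the direction of its test turned, or SGC0946 B (0.984 and 0.0578). Medians also moved: cholesterol synthesis was at −0.332 without DMSO A and −0.014 without DMSO B, and the interferon list at 0.321 and 0.082. With quantile scaling the interferon median was 0.03 with 2 genes higher, and the lymphoid median 0.17. MYC targets were not called (1 of 41 higher, median −0.04 but 0.03 with quantile scaling, camera adjusted p = 0.653), nor were BET response markers (2 of 9 lower, median −0.25, camera adjusted p = 0.102). Stem and progenitor genes had a median of 0.54 (6 of 14 higher and 2 lower, camera adjusted p = 0.0501).

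In all, limma called 1397 genes for SGC0946 against DMSO, 757 higher and 640 lower. Of the 286 that changed at least 2-fold, 231 were higher and 55 lower. The count rested on each library: it was 794 without DMSO A, 728 without DMSO B, 422 without SGC0946 A and 417 without SGC0946 B, and 475 at an adjusted p under 0.01. With blocks of libraries chosen after seeing the data it was 892 (by depth order) and 2518 (by an orientation picked from the residuals, which favours calls).

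With both inhibitors, MYC was at 127 ± 33.8 CPM (log2 fold change −1.90 against DMSO, SE 0.14, limma adjusted p = 6.74e-06), BCL2 at 55.7 ± 10.6 CPM (log2 fold change −2.06, SE 0.12, limma adjusted p = 2.23e-06) and HEXIM1 at 199 ± 23.1 CPM (log2 fold change 1.77, SE 0.11, limma adjusted p = 3.03e-06). CDK6 and MYB fell by 1.24 and 0.52 and BRD2 rose by 0.55 on the log2 scale (limma adjusted p = 1.17e-05, 0.000621 and 0.000228). DOT1L fell by 0.34 (limma adjusted p = 0.00648, but 0.055 without library B of the combination). HOXA9, HOXA10 and MEIS1 had log2 fold changes of −0.20, −0.22 and −0.25 (limma adjusted p = 0.151, 0.0984 and 0.0898). The largest rises were those of EFR3B (4.05), RTL5 (3.94), DPYSL3 (3.5), CAPN5 (3.48), SEMA6C (3.46), FGD6 (3.39), H2BC5 (3.28), ARRDC3 (3.16), SAT1 (3.11) and H2AC6 (3.09), and the largest falls those of CHAC1 (−4.71), HSH2D (−4.46), LGALS12 (−4.30), CSPG4 (−4.12), ADM2 (−4.01), CCR2 (−3.87), NAV3 (−3.59), INHBA (−3.5), SLC7A11 (−3.42) and PHACTR3 (−3.35). All 20 kept their call without any single library.

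Of 41 MYC targets 36 fell and 1 rose in the combination, with a median log2 fold change of −0.98 (camera adjusted p = 1.55e-13, and adjusted p = 0.516 with an estimated correlation). Of 24 stress genes 14 fell, with a median of −0.76 (camera adjusted p = 1.64e-05, and adjusted p = 0.483 with an estimated correlation). Of 21 MLL fusion targets 11 fell and 1 rose, with a median of −0.30 (camera adjusted p = 0.000308, and adjusted p = 0.516 with an estimated correlation), FLT3 falling by 0.90 and MEF2C by 0.86. Of 33 DNA replication genes 16 fell and 1 rose (median −0.24, camera adjusted p = 0.0016, and adjusted p = 0.562 with an estimated correlation), led by MCM2 (−1.06), MCM5 (−0.88) and MCM6 (−0.83), subunits of the replicative helicase. Of 24 cholesterol synthesis genes 14 fell and 1 rose (median −0.52, camera adjusted p = 0.0016, and adjusted p = 0.596 with an estimated correlation), with INSIG1 at −1.09 and DHCR7 at −1.06, while TM7SF2 rose by 1.96. Of 22 differentiation genes 14 fell and 2 rose (median −0.84, camera adjusted p = 0.0016, and adjusted p = 0.561 with an estimated correlation). Of 8 MHC class II genes 6 rose and 2 fell (median 1.22, camera adjusted p = 0.0267, and adjusted p = 0.516 with an estimated correlation). HLA-DRA rose to 24.5 ± 0.17 CPM (log2 fold change 2.69), whereas CIITA fell to 2.31 ± 0.53 CPM (log2 fold change −1.13, SE 0.21, limma adjusted p = 0.00159). Of 9 BET response markers 8 rose and 1 fell (median 1.77, camera adjusted p = 4.91e-05, and adjusted p = 0.475 with an estimated correlation). Of 14 stem and progenitor genes 7 fell and 1 rose (median −0.48, camera adjusted p = 0.0202, and adjusted p = 0.516 with an estimated correlation), a call lost without library A of the combination (median −0.265, camera adjusted p = 0.0719). Without DMSO B the medians of the stem and progenitor and cholesterol lists were −0.319 and −0.346, both still called. Of 28 mitosis genes 5 were higher and 4 lower (median −0.02 but 0.09 with quantile scaling). With median-of-ratios and quantile scaling 2 and 9 were higher and 4 and 3 lower. Mitosis genes were not called (camera adjusted p = 0.86), nor were heat shock, housekeeping, BCL2 family and BRD and DOT1L complex genes (camera adjusted p = 0.653, 0.545, 0.434 and 0.468). Adjusted over the list alone, 38 MYC targets, 16 stress genes and 12 MLL fusion targets fell. The balance of directions moved with the scaling, as 2763 genes were higher and 3104 lower with median-of-ratios. In all, limma called 5945 genes for the combination against DMSO in the main fit, 3052 higher and 2893 lower, and 1294 of them changed at least 2-fold. Without library A of the combination 1961 were higher.

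**Figure D3:**
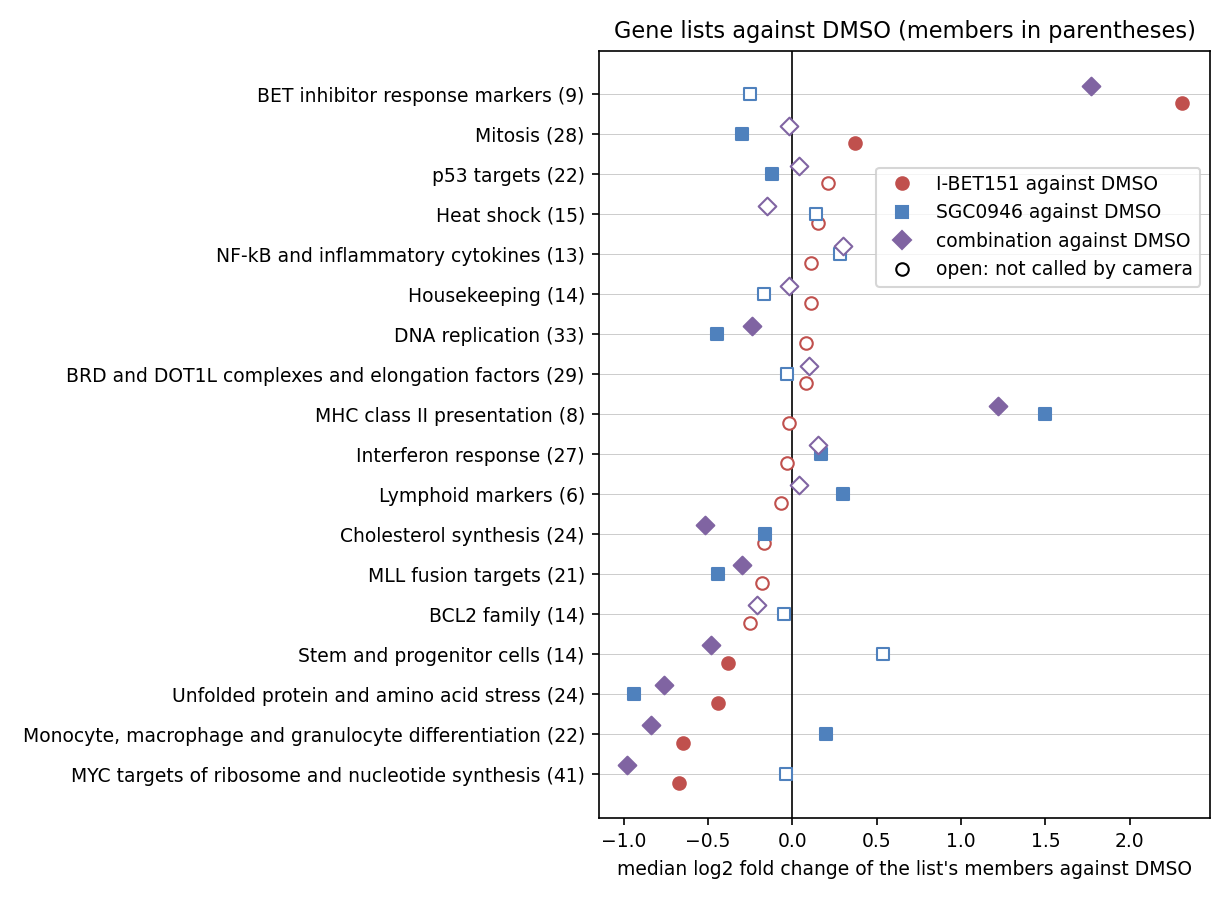
Median log2 fold change against DMSO (horizontal axis) of the tested members of 18 gene lists (vertical axis, number of members in parentheses) for I-BET151 (circles), SGC0946 (squares) and the combination (diamonds), filled where camera with its preset correlation called the list. MYC targets lie at −0.67, −0.04 and −0.98, and MHC class II genes at −0.02, 1.5 and 1.22, where the −0.04 became 0.03 and the −0.02 became 0.05 with quantile scaling. No list was called with an estimated correlation.

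Set against I-BET151 alone, the combination shows what SGC0946 added. HOXA9 fell by 0.96 and HOXA10 by 0.93 on the log2 scale (SE 0.11 and 0.10, limma adjusted p = 0.00142 and 0.0012). The largest rises were those of HLA-DRA (log2 fold change 2.75), PLXNB1 (1.94), CYP1B1 (1.90), KLF12 (1.90) and F13A1 (1.85), and the largest falls those of CHAC1 (−2.41), PPP1R27 (−1.41), CSPG4 (−1.36), SREBF1, a regulator of lipid synthesis (−1.34), and FCGR1A (−1.31). CYP1B1, CHAC1 and CSPG4 lost the limma call without a library of the combination, and CYP1B1 also without I-BET151 A (adjusted p up to 0.0869, 0.0827 and 0.0866). Of 33 replication genes 19 fell (median −0.39, camera adjusted p = 3.16e-15, and adjusted p = 0.292 with an estimated correlation), of 28 mitosis genes 10 fell (median −0.26, camera adjusted p = 6.87e-09, and adjusted p = 0.385 with an estimated correlation), and of 8 MHC class II genes 6 rose (median 1.08, camera adjusted p = 8.36e-07, and adjusted p = 0.292 with an estimated correlation). Lists that fell as well were stress genes (6 of 24, median −0.38, camera adjusted p = 3.55e-06), MYC targets (5 of 41, median −0.24, camera adjusted p = 5.2e-06), cholesterol synthesis (5 of 24, median −0.29, camera adjusted p = 9.31e-06) and MLL fusion targets (7 of 21, median −0.18, camera adjusted p = 0.00185), with adjusted p = 0.292, 0.571, 0.462 and 0.462 with an estimated correlation. The MLL call was lost without I-BET151 B (median −0.061, camera adjusted p = 0.0606), and its median was −0.10 with quantile scaling. Medians moved as well without I-BET151 A for MYC targets (−0.108) and stress genes (−0.625), and without I-BET151 B for MYC targets (−0.369) and cholesterol synthesis (−0.436). Of 27 interferon response genes 6 rose and 1 fell (median 0.28, camera adjusted p = 0.0113, and adjusted p = 0.385 with an estimated correlation), but with quantile scaling 3 rose and the median was 0.11. Calls of heat shock, housekeeping and BET response genes (medians −0.22, −0.08 and −0.27, camera adjusted p = 0.0207, 0.0149 and 0.0342, and adjusted p = 0.672, 0.59 and 0.385 with an estimated correlation) were each lost without I-BET151 A (0.386, 0.146 and 0.0507) and without a library of the combination (0.0861 for B, 0.138 for A and 0.0998 for B), the last also without I-BET151 B (0.0581). The heat shock median was −0.08 without I-BET151 A, −0.331 without I-BET151 B and −0.115 without library B of the combination. The housekeeping median was −0.04, −0.143 and −0.205 without the same libraries, and −0.05 without library A of the combination. MYC and BCL2 had log2 fold changes of 0.33 and −0.29 (limma adjusted p = 0.15 and 0.142). Fold changes of this comparison rose with gene length across genes (Spearman's rho = 0.168 for genomic and 0.235 for exonic length), and so may partly reflect the libraries, since the difference of the 2 I-BET151 libraries (A minus B) also followed length (−0.141 and −0.295). With median-of-ratios scaling 808 genes were higher and 750 lower. In the main fit limma called 1560 genes in all, 911 higher and 649 lower, 228 of them at least 2-fold. The count was 278 without library A of the combination, 255 without its library B, 385 without I-BET151 A, 988 without SGC0946 A, 992 without SGC0946 B and 363 at an adjusted p under 0.01, and 854 and 3124 with the blocks by depth order and by orientation.

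Set against SGC0946 alone, the combination shows what I-BET151 added. MYC fell by 2.28 and BCL2 by 1.78 on the log2 scale (SE 0.14 and 0.12, limma adjusted p = 5.48e-06 and 7.73e-06). HEXIM1 rose by 1.80, HOXA9 by 0.74 and HOXA10 by 0.86 (limma adjusted p = 4.89e-06, 0.000456 and 0.000116). EFR3B (3.81), CAPN5 (3.38), H2AC6 (3.35), FGD6 (3.02) and DPYSL3 (2.96) rose most and CCR2 (−4.72), HSH2D (−4.05), LGALS12 (−3.93), CSPG4 (−3.91) and IL7R, a cytokine receptor (−3.63), fell most. Of 41 MYC targets 35 fell (median −0.93, camera adjusted p = 1.54e-14, and adjusted p = 0.464 with an estimated correlation), and of 28 mitosis genes 12 rose (median 0.29, camera adjusted p = 0.000576, and adjusted p = 0.501 with an estimated correlation). Differentiation genes (13 of 22 lower), stem and progenitor genes (9 of 14 lower, 1 higher) and BET response markers (8 of 9 higher, 1 lower) were also called (camera adjusted p = 1.37e-05, 0.00128 and 5.15e-06, and adjusted p = 0.464, 0.464 and 0.328 with an estimated correlation). In all, limma called 5259 genes, 2622 higher and 2637 lower, 1043 of them at least 2-fold. The count was 3305 without library A of the combination, 3500 without SGC0946 A (1722 higher genes without SGC0946 B) and 3385 at an adjusted p under 0.01.

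The inhibitors were also compared directly. MYC was lower with I-BET151 than with SGC0946 by a log2 difference of −2.61 and BCL2 by −1.49, while HOXA9 was higher by 1.71 and HOXA10 by 1.79 (SE 0.14, 0.12, 0.11 and 0.10, limma adjusted p = 1.53e-06, 1.04e-05, 2.6e-06 and 1.53e-06). H2AC6 (3.62), H2BC11 (3.58), EFR3B (3.46), SERPINI1 (3.37) and the metallothionein gene MT2A (3.2) were furthest higher with I-BET151, and CCR2 (−5.42), NFE2 (−3.93), GRIP1 (−3.81), SLC1A3 (−3.76) and MYBPH (−3.74) furthest lower. Of 28 mitosis and 33 replication genes, 23 and 23 were higher with I-BET151 (medians 0.57 and 0.58, camera adjusted p = 9.08e-09 for each, and adjusted p = 0.301 for each with an estimated correlation). All 8 MHC class II genes were lower (median −1.38, camera adjusted p = 7.62e-06, and adjusted p = 0.23 with an estimated correlation). Differentiation genes (17 of 22 lower, 2 higher), MYC targets (32 of 41 lower, 1 higher), stem and progenitor genes (10 of 14 lower, 2 higher), p53 targets (11 of 22 higher, 2 lower), BET response markers (8 of 9 higher, 1 lower), BRD and DOT1L complex genes (12 of 29 higher, 3 lower) and stress genes (8 of 24 higher, 1 lower) were also called by camera (adjusted p from 2.04e-08 to 0.0475, and adjusted p from 0.23 to 0.414 with an estimated correlation). The stress call was lost without SGC0946 B (camera adjusted p = 0.0913) or I-BET151 B (0.0871), its median of 0.27 being 0.168 without SGC0946 B and 0.408 without SGC0946 A. The median of the p53 targets was 0.45, and 0.285 without I-BET151 B. In all, limma called 5857 genes, 2824 higher with I-BET151 and 3033 lower, 1350 of them at least 2-fold.

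Among genes called for each single agent against DMSO, 420 moved in the same direction and 357 in opposite directions. Independent lists of these sizes would share 286.7 and 288.3. Simulated unchanged groups that share the DMSO libraries gave 0 of either. With no condition changed almost no gene is called, so this cannot show how many shared calls come from the shared libraries. The same-direction count was 240 and 273 without DMSO A and B, 143 and 137 without SGC0946 A and B, and 134 at an adjusted p under 0.01. The opposite-direction count was 163, 130, 108 and 110 without the same libraries and 96 at 0.01. Across the 12192 genes, which are not independent replicates, the fold changes of the single agents had Pearson's r = 0.042 and Spearman's rho = 0.048. Simulated unchanged groups with the shared DMSO libraries gave r = 0.502. That value is for noise alone, so the observed r cannot be set against it directly. The covariance was 0.009 against a simulated 0.0169, a difference of −0.0079. With 1 DMSO library for each agent, r was −0.065 or −0.028 depending on which library went to which agent, and it was 0.122 without DMSO A and 0.123 without DMSO B. With 2 DMSO libraries, the controls could not be split with 2 for each agent.

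The effect of each agent was also compared with and without the other, where no library is shared. Of genes called for SGC0946 in DMSO and in I-BET151, 745 moved in the same direction and 1 in opposite directions, against 90.6 and 88.1 for independent lists (Pearson's r = 0.71 across genes, −0.004 in simulated unchanged groups). The 745 fell to 205 without library A of the combination, 196 without its library B, 432 without DMSO B, 282 without SGC0946 A, 275 without SGC0946 B, 304 without I-BET151 A and 189 at an adjusted p under 0.01, with 0 to 6 in opposite directions. For I-BET151 in DMSO and in SGC0946, 3952 moved in the same direction and 2 in opposite directions, against 1082.4 and 1082.1 (Pearson's r = 0.895, −0.001 simulated). Without 1 library these were 2768 to 3747 and 0 to 16, and at an adjusted p under 0.01 they were 2433 and 1. In the combination, 217 genes were higher and 248 lower than with either agent alone, against 195.9 and 140.4 for independent lists, while 370 lay between the agents, higher than with 1 and lower than with the other, against 336.6. Across genes the correlation of the 2 comparisons was Pearson's r = 0.077. Simulated unchanged groups, which share the libraries of the combination, gave 0.501, but from noise alone, so the 2 values are not alike. The covariances were near equal (0.0165 and 0.0168 simulated). Independent lists leave out the shared libraries of the combination, so counts above theirs may come from that sharing. Without 1 library the 217, 248 and 370 were 31 to 322, 30 to 388 and 60 to 433, lowest without a library of the combination, and at an adjusted p under 0.01 they were 41, 44 and 86. By the smaller of their 2 fold changes these were led by SNPH, RTL5, PPP1R27, ARRDC3, CSPG4 and FOSL1, chosen after their values were seen.

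The interaction asks whether the combination departed from the sum of the single agents' log2 fold changes. Genes above 1 CPM in only 1 condition are absent from the values and could not be tested. No gene was called by limma (lowest adjusted p = 0.107, for ZBTB33) and none by limma-voom on the separated reads, with 771 genes at an unadjusted p under 0.05 where 609.6 are the share that chance gives. The interaction was −0.05 for MYC, 0.16 for HOXA10, 0.31 for MEIS1 and 0.72 for CDK6 (SE 0.20, 0.14, 0.16 and 0.15, limma adjusted p = 0.974, 0.855, 0.79 and 0.471). Its median SE was 0.183, and on simulated reads the interaction test called 36.2% of genes changed 1.5-fold, 81.2% of those changed 2-fold and 39 of 40 changed 4-fold. These reads had the same spread beyond counting noise in every gene, so the shares can overstate what the test finds here. IGF1, picked after its value was seen, had an interaction of −2.22 (SE 0.4) and was not called (limma adjusted p = 0.274). Without DMSO B, 2 genes were called: SESN2 (2.75, SE 0.26, limma adjusted p = 0.0158) and ZBTB33 (1.13, SE 0.13, limma adjusted p = 0.0378). These 2 genes were named after their values were seen. The libraries also shared a structure across conditions: NEAT1 and MALAT1 were higher, and FOS and EGR1 lower, in DMSO A, SGC0946 B, I-BET151 B and library A of the combination than in the other library of the same condition. NEAT1 was at 281.8 against 136 CPM in DMSO, 232 against 159.6 in SGC0946, 537 against 275 in I-BET151 and 612 against 317 in the combination. A block on these sides, picked from the residuals of the same libraries after seeing the data and so favouring calls, called 8 genes for the interaction, led by CHI3L1 (−1.45, limma adjusted p = 0.00232) and ZBTB33 (1.03, limma adjusted p = 0.00347), with UNC5C, GNAQ, PPP1R27, TENT5A, TTBK2 and SESN2. Whether the sides are replicates or batches is not given, so the count of 0 holds for the fit without a block. Of 18 lists, 9 were called for the interaction by camera with its preset correlation and 0 with an estimated correlation, and their values stand in the closing section.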

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

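The tests of a raised DMSO library and of growth state below were chosen after the result was seen, and the tests of length and scaling were written before the list medians they measure were seen, but after length trends over all genes and counts of calls under median-of-ratios scaling had been. Each of the 9 lists here differed between the effect of SGC0946 in DMSO and in I-BET151 by the interaction test (camera with its preset correlation). None was called with an estimated correlation (adjusted p from 0.528 to 0.611), and limma called 0 genes for the interaction (771 at an unadjusted p under 0.05, and 0 called by limma-voom).

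MLL fusion targets lay above additivity, with a median interaction of 0.31 (camera adjusted p = 1.65e-08, and adjusted p = 0.538 with an estimated correlation): the median log2 fold change with SGC0946 was −0.44 in DMSO and −0.18 in I-BET151. Adjusted over the list alone, 7 of 21 members lay above additivity and 0 below it, but fry did not call the list (adjusted p = 0.332). Interaction values rose with gene length across genes (Spearman's rho = 0.267 for genomic and 0.244 for exonic length), but after removal of that trend the list median was 0.21 and stayed at percentile 100 (rounded) of 10000 random lists of matched expression, which argues against length as the whole cause, although part of the value went with it. Leaving out each library in turn left it at 0.19 (without I-BET151 A) or more. This argues against a single library as the whole cause, although part of the value went with I-BET151 A. The difference of the I-BET151 libraries (A minus B) also followed length (Spearman's rho = −0.141 for genomic and −0.295 for exonic length). Length and this library were not removed together, so their joint share is not known. A difference in the effect of SGC0946 itself between DMSO and I-BET151 stays open, and no test of it beyond the interaction was run.

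The stress list fell with SGC0946 by a median of −0.94, and had an interaction of 0.38 (camera adjusted p = 0.00226, and adjusted p = 0.538 with an estimated correlation), the median being −0.38 in I-BET151. The interaction was 0.119 without DMSO A and 0.246 without I-BET151 A. Without either DMSO library the fall was still −0.69 or further from 0, which argues against a single raised DMSO library as its whole cause. The 13 called members differed between the DMSO libraries by a median of 0.92, against a change of 1.43. The growth or feeding state of the cultures therefore cannot be told apart from an effect of the inhibitor for these genes, because such genes moved without treatment and culture conditions were not recorded in the values.

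The mitosis list rose with I-BET151 by a median of 0.37, and of 0.231 without DMSO A. It was 0.36 with median-of-ratios scaling, which moved the median of all genes by only −0.005, and 0.39 with quantile scaling. The median of all genes was 0.003. As median-of-ratios scaling moved all genes so little, the list median could hardly have changed, so this test does not decide about scaling. A factor common to all genes would move the list and the other genes alike. Whether all genes shifted together cannot be seen, because scaling removes it. Fold changes had almost no length trend (Spearman's rho = −0.031 for genomic and −0.006 for exonic length). After its removal the list median was 0.41, at percentile 100 (rounded) of random lists of matched expression. With almost no trend to remove, the median could hardly have fallen, so this test does not decide about length. No biological explanation was tested.

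Medians of the interaction in the other lists follow. Heat shock genes were at −0.36 (camera adjusted p = 2.91e-06), not called without DMSO A, where the median was −0.077 (0.0576), and at −0.678 without DMSO B and −0.22 without I-BET151 A. MYC targets were at −0.21 (camera adjusted p = 7.03e-08), and at −0.103 without DMSO A, −0.347 without DMSO B, −0.106 without I-BET151 A and −0.337 without I-BET151 B. Lymphoid markers were at −0.25 (camera adjusted p = 0.0043), and at −0.382 without library A of the combination. Cholesterol synthesis was at −0.15 (camera adjusted p = 0.00573), not called without I-BET151 A, where the median was −0.032 (0.307), or DMSO A, where it was 0.04 (0.921), and at −0.266 without DMSO B. MHC class II presentation was at −0.27 (camera adjusted p = 0.00848), not called without DMSO B, where the median was −0.14 (0.118), SGC0946 B, where it was −0.127 (0.0961), or I-BET151 B, where it was −0.232 (0.0905), and at −0.412 without SGC0946 A. DNA replication was at 0.10 (camera adjusted p = 0.00979), not called without DMSO B, where the median was 0.08 (0.479), or I-BET151 B, where it was 0.017 (0.583), and at 0.179 without I-BET151 A. Stem and progenitor genes were at −0.33 (camera adjusted p = 0.0241), not called without library A of the combination, where the median was −0.269 (0.283), DMSO A, where it was −0.388 (0.0576), DMSO B, where it was −0.383 (0.0584), or I-BET151 A, where it was −0.19 (0.181).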

How the results depend on the processing

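Settings chosen after seeing the data are limma-voom, both library blocks and all those of the last 3 overlaps below. No paired analysis was possible because the values carry no replicate numbers. A block by depth order within a condition, which pairs nothing, gave 892 genes for SGC0946 and 854 for the combination against I-BET151. A block by the orientation of libraries, picked among 8 from the residuals of the same values to make deviations correlate between conditions (r from 0.068 to 0.478), gave 2518, 3124 and, for the interaction, 8 genes. Such a choice favours calls by construction, and neither block changes a fold change. The planned count tests with edgeR and DESeq2 were not run. No filter left the genes as they were and tests nothing.

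Counts of 5018 (I-BET151), 1397 (SGC0946), 5945 (combination), 1560 (combination against I-BET151), 5259 (against SGC0946), 5857 (between agents) and 0 (interaction) stayed within 1.5 times under both pseudocounts, the 5 CPM filter, both scalings, the robust prior, voom and fits of only the conditions compared. The last of these settings was not run for the interaction, which uses all 4 conditions. By construction a 2-fold minimum gave 1016, 286, 1294, 228, 1043 and 1350, and an adjusted p under 0.01 gave 3187, 475, 363 and 3385 for I-BET151, SGC0946, and the combination against I-BET151 and against SGC0946. With fewer samples, leaving out 1 library gave 417 to 1654 (SGC0946), 255 to 2044, 3305 to 5579 and 0 to 2 (interaction). The lone library is assumed to vary like the other conditions. Such fits have less power, so a lost call does not by itself mark a single library as its source. The other counts stayed within 1.5 times. Under another scaling the median over all genes shifted by less than 0.1, the largest shift being −0.039, but list medians moved more, as that of interferon genes with SGC0946 from 0.17 to 0.03. The split into higher and lower genes moved too. For the combination against DMSO 51.3% of called genes were higher, 47.1% with median-of-ratios and 50.8% with quantile scaling. Against I-BET151 these were 58.4%, 51.9% and 54.3%.

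Lists called by camera fell to 0 in every comparison with an estimated correlation. Fry called 10 for I-BET151, 5 and 11 for the combination against I-BET151 and SGC0946, and 0 for the interaction. In either direction fry called 17, 18, 17, 16 and 1 for I-BET151, the combination, the combination against SGC0946, I-BET151 against SGC0946, and the interaction. Correlation among members is not the whole cause of the lost camera calls. The p53 targets with SGC0946, at an estimated correlation of 0.01, went from camera adjusted p = 0.0198 to 0.191. Lymphoid markers in the interaction, at an estimated correlation of −0.032, went from camera adjusted p = 0.0043 to 0.528. Camera with an estimated correlation also uses only the 4 residual degrees of freedom, which leaves less power than the preset. How much each part contributes was not tested. Leaving out a library gave 5 to 10 lists called by camera with its preset correlation for the combination against SGC0946. Cholesterol synthesis turned direction without DMSO B for SGC0946 (medians −0.332 to −0.014 over libraries left out) and without DMSO A for the interaction (−0.266 to 0.04).

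The overlap of 420 genes was 134 at 0.01 and 137 to 439 without 1 library, and the opposite 357 was 96 and 108 to 398. SGC0946 effects with and without I-BET151 (745 same, 1 opposite) were 189 and 0 at 0.01 and 196 to 814 and 0 to 6 without 1 library. I-BET151 effects with and without SGC0946 (3952 and 2) were 2433 and 1, and 2768 to 3747 and 0 to 16. Genes of the combination higher than, lower than and between the agents (217, 248 and 370) were 41, 44 and 86, and 31 to 322, 30 to 388 and 60 to 433. The correlation of 0.042 turned to −0.065 and −0.028 with 1 DMSO library each, and was 0.006 to 0.123 without 1 library. Uncalled values near 0 turned sign, the cause not tested. DOT1L with I-BET151 was 0.064 under quantile scaling, BRD2 in the combination against I-BET151 was 0.002 under it, and BCL2 in the interaction was 0.001 at pseudocount 1. Ranges without 1 library were MEIS1 −0.191 to 0.056 and DOT1L −0.085 to 0.074 with I-BET151 and HEXIM1 −0.12 to 0.06 with SGC0946. They were CDK6 −0.062 to 0.237 for the combination against I-BET151 and MYB −0.084 to 0.052 between agents. Of interactions they were MYC −0.319 to 0.229, BCL2 −0.194 to 0.193, HOXA9 −0.135 to 0.107, MYB −0.123 to 0.014 and HEXIM1 −0.229 to 0.007. Of the called named genes, 75 of 85 for I-BET151, 32 of 71 for SGC0946, 80 of 89 for the combination, 20 of 65 and 66 of 78 for it against I-BET151 and SGC0946, and 68 of 79 between agents kept their call without any single library. Depth of 13843940 to 16900030 reads limits genes near 1 CPM.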

Other observations

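The 21 gene families in this part, and so all of their tests, were chosen after the values were seen, from families that stood out or were looked at beside them, so their p-values are descriptive. A family is the set of genes whose symbols match its name, which can include pseudogenes, antisense and neighbouring genes. As poly(A) RNA was sequenced, histone transcripts without a poly(A) tail are not covered. Histone genes rose with I-BET151 (27 of 29, median log2 fold change 1.18, camera adjusted p = 9.4e-14, and adjusted p = 0.178 with an estimated correlation), which overlaps with the BET response markers in 5 genes, and in the combination 25 rose and 1 fell (median 1.07). With SGC0946 alone 1 rose and 5 fell (median −0.16, and −0.24 with quantile scaling). Metallothioneins, which bind metals, rose with I-BET151 in 5 of 5 genes (median 1.6, camera adjusted p = 0.000277, and adjusted p = 0.425 with an estimated correlation) and fell with SGC0946 in 4 of 5 (median −0.58, camera adjusted p = 7.2e-05, and adjusted p = 0.341 with an estimated correlation). In the combination 3 of 5 were higher (median 0.65) and camera did not call them (adjusted p = 0.128, and 0.517 with an estimated correlation), and with quantile scaling 2 were higher and 1 lower (median 0.50). Cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs, fell with I-BET151 (12 of 17, median −0.62), SGC0946 (9 of 17, median −0.51) and the combination (13 of 17, median −1.10), with camera adjusted p = 0.000637, 6.05e-09 and 3.42e-06, and adjusted p = 0.432, 0.265 and 0.33 with an estimated correlation.

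In the combination, cytosolic ribosomal protein genes rose (46 of 81, 4 lower, median 0.26) while mitochondrial ribosomal protein genes fell (46 of 74, 2 higher, median −0.40), as did CCT chaperonin genes (8 of 9, median −0.58, but 7 of 9 and −0.35 with quantile scaling) and proteasome genes (19 of 37, 1 higher, median −0.28), with camera adjusted p = 8.09e-06, 3.9e-08, 0.00458 and 0.00083, and adjusted p = 0.517 for each with an estimated correlation. Cytosolic ribosomal protein genes had a median of 0.25 with SGC0946 alone (12 of 81 higher, 1 lower, camera adjusted p = 1.75e-11, and adjusted p = 0.392 with an estimated correlation). In the combination against SGC0946 their median was 0.03 (camera adjusted p = 0.641). Under median-of-ratios and quantile scaling 34 and 55 of them rose in the combination, and 5 and 39 with SGC0946. Plexins and semaphorins, guidance receptors and ligands, rose with SGC0946 in 7 of 21 genes (median 0.46, camera adjusted p = 3.91e-05, and adjusted p = 0.392 with an estimated correlation). Genes with HLA symbols, which include pseudogenes and an antisense gene and of which 5 stand in the fixed lists, rose with SGC0946 (9 of 14, median 0.65) and in the combination (12 of 14, median 0.78). Of 6 genes with SLC7A symbols, which are amino acid transporters except for SLC7A6OS, a neighbouring gene on the other strand, 5 fell with I-BET151 and 4 in the combination, SLC7A6OS not being among them. Of 8 HOX genes, 2 rose and 5 fell with I-BET151. Genes with ZNF symbols and those with RAB symbols were not called by camera against DMSO in any of the 3 treatments (lowest adjusted p = 0.13). The family matched for immediate early genes also held many DUSP genes and others that are not immediate early genes, so no result is given for it. No family was called with an estimated correlation (lowest adjusted p = 0.178 over 7 comparisons).

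CIITA and the genes it activates moved apart in the combination. CIITA was at 5.70 CPM in DMSO, 18.05 with SGC0946, 1.91 with I-BET151 and 2.31 with both, while HLA-DRA was at 3.40, 32.1, 3.25 and 24.5 CPM and CD74 at 124 CPM in DMSO and 325 with both. The interaction of CIITA was −1.40 (limma adjusted p = 0.485). FOS, an immediate early gene, differed between the libraries of every condition, at 20.0 and 76.2 CPM in DMSO A and B, 85.3 and 12.2 in I-BET151, 36.4 and 8.67 in SGC0946, and 10.5 and 109 in the combination.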
